A study of Homo sapiens with 4 samples.

How the data were processed

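RNA was measured in 4 libraries of HCT116, a human colon carcinoma line. 2 libraries came from wild-type (WT) cells and 2 from clone E2-4, made with CRISPR and a guide RNA against exon 2 of TOP3B (knockout, KO). Per the labels' protocols, total RNA was extracted with TRIzol, its RNA integrity numbers were above 8.0, ribosomal RNA was removed with Ribo-Zero beads, and stranded libraries were sequenced as pairs of 150 bp reads on a HiSeq instrument in a pool of 12 libraries. The labels do not say whether the 2 libraries of a group came from separate cultures. P-values of single genes therefore measure the spread between these libraries. Those of gene lists with a preset correlation compare genes with other genes, and those of runs of adjacent genes come from random gene orders. The comparison is of 1 clone with its parental line.

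The authors deposited a table of estimated read counts per gene and a table of RPKM for the same libraries. Salmon 1.10.1 and the build hg19 are named in the submitters' processing notes; the annotation, the summary of transcripts to genes and any filter are not given in the sources used here. The deposited counts were whole numbers, and RPKM values of the same genes implied estimates that were not whole before rounding, so the counts were treated as rounded estimated counts. From the values, the deposited RPKM are these counts divided by gene length and by the column sum, with no further scaling factor. The gene lengths implied by RPKM tracked the genomic span of genes (Spearman's rho 0.941 across 11775 genes), with a median of 0.584 of the span, so RPKM of genes with long introns are lower than a transcript length would give. Both tables held 35820 rows, of which 16471 had a count of 0 in every library. 1 row carried different names in the 2 tables, which left 35819 genes for steps that used both.

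An estimated count can fall to 0 in one library and not in another because of how shared reads are divided. Several genes that every cell uses had low estimates, such as ACTB with 426, 507, 600 and 1006 counts (WT replicates 1 and 2, then KO replicates 1 and 2) against 139006, 99439, 99621 and 145053 for TUBA1B. Levels were therefore compared between libraries for one gene and not between genes, and genes that overlap or share sequence with a copy, readthrough genes included, are uncertain.

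Of the rows, 99.2% were matched by symbol to GENCODE 29 (GRCh38). That annotation was used for identifiers, chromosomes, gene order, genomic span and GC content only. No coordinates are given, since the authors' build differs.

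The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; estimateDisp, glmQLFit, glmQLFTest) with TMM factors and filterByExpr, on genotype alone, with Benjamini-Hochberg adjustment and a threshold of 0.05. It tested 12269 genes. CPM values are counts scaled by the library size times the TMM factor. The standard error of an edgeR log2 fold change is its size divided by the square root of the F statistic. DESeq2 1.42.0 (Wald test, default settings) was the first alternative and gave an adjusted p for 12899 genes. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound. Floors cover counting error only, and 3 counts correspond to 0.176 to 0.271 CPM in a single library.

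34 gene lists were tested or described: hypoxia response and glycolysis, epithelial, cholesterol synthesis, YAP/TAZ targets, cytosolic ribosomal proteins, WNT/beta-catenin targets, replication-dependent histones, neuronal and synaptic, intestinal stem cell, R-loop processing factors, mesenchymal, immediate early, translation factors, ribosome biogenesis and MYC targets, NF-kappaB targets, proliferation, TOP3B partners and the FMRP family, topoisomerases with tyrosyl-DNA phosphodiesterases, cancer-testis, homologous recombination, stress response, interferon-stimulated, mitochondrially encoded mRNAs, TOP3B neighbours, p53 targets, MAPK output, nuclear RNA surveillance, intestinal differentiation, metallothioneins, and markers of endothelial, erythroid, fibroblast, hepatocyte and kidney, and leukocyte cells. Lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over the lists, and also with an estimated correlation and with fry. For DESeq2 the lists were tested with cameraPR on its Wald statistic. Gene length was compared with fold change by Spearman's rho and, for genes over 100 kb, by camera; chromosomes were tested with camera as sets. Groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined.

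Named genes were TOP3B and TDRD3, up to 10 genes each way with the largest edgeR change among those past the threshold (at least 5 CPM in the higher group, both KO libraries on the same side of both WT libraries), and in each list the 4 tested members with the smallest p; Y-linked genes and XIST were left out. As edgeR called 1 gene, the same rule was also applied to the DESeq2 calls, a step added after the data were seen.

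The code was tested on counts simulated from these libraries' means, sizes and spread (12269 genes, 5 simulations, KO against WT). At a true 2-fold change edgeR recovered 19.6% of changed genes and DESeq2 38.4%; at 4-fold these were 63.6% and 71.6%. Of the genes called in the simulations, 14.7% were unchanged for edgeR and 28.3% for DESeq2. Over the 5 simulations edgeR called 419 changed and 72 unchanged genes, against 1 gene in the data. The simulated shares may therefore not carry over to the data. Camera gave p under 0.05 for 3.4% of 1000 random sets with the preset correlation and for 0 with an estimated one. Both gave p under 0.05 for a set of 30 genes shifted by -0.6 (log2) in 5 of 5 simulations. These p were not adjusted, so they do not show what passes after adjustment over the lists. The simulated genes were also drawn independently of each other. The share for random sets therefore does not show how often camera errs for lists whose genes vary together.

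Alternatives covered other scaling factors, filters on low counts, DESeq2, limma-voom, limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1), the replicate number as a block, other thresholds and set tests, and leaving out each library in turn. Those added after the data were seen were robust edgeR dispersions, a GC correction, genes with no 0 in any library, and DESeq2 refits. Random gene orders were drawn with numpy 2.4.6 and figures with matplotlib 3.10.9.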

Results

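RNA levels were compared between wild-type HCT116 cells and cells of clone E2-4, in which TOP3B had been targeted, with 2 libraries of ribosomal-RNA-depleted total RNA in each group. TOP3B is a topoisomerase that acts on both RNA and DNA, and the series asks how its loss affects transcription and R-loops, the RNA-DNA hybrids that form behind RNA polymerase. The WT libraries held 15141919 and 11750516 estimated counts in genes, and the KO libraries held 10450048 and 16143634. A count of 0 in a single library allows a level of up to 0.176 to 0.271 CPM, and such floors cover counting error only. Tests of single genes measure the spread between these libraries, while camera with the preset correlation compares genes of a list with other genes. Clone and genotype cannot be separated, as there was 1 KO clone. The TMM factor of WT replicate 1 was 0.858, against 1.04 to 1.06 in the other 3 libraries. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.960 within each group. Between groups it was 0.937 and 0.935 for WT replicate 1 with the KO libraries and 0.951 and 0.954 for WT replicate 2. The share of genes over 2-fold apart was 10.4% between the WT libraries and 8.47% between the KO libraries. For WT replicate 2 this share was 10.7% with KO replicate 1 and 9.81% with KO replicate 2. It was higher for WT replicate 1 with either KO library. By this share WT replicate 2 was about as close to the KO libraries as to WT replicate 1. The small noncoding RNAs RN7SK, SNORD3A and RMRP together took 11.4% and 9.90% of counts in the WT libraries and 7.78% and 7.33% in the KO libraries.

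The TOP3B transcript was still present in the KO clone. Its level was 57.1 and 66.5 CPM in the WT libraries and 43.9 and 54.7 CPM in the KO libraries, with group means of 61.8 ± 6.65 and 49.3 ± 7.60 (SD, n = 2 each). The log2 fold change was -0.32 (SE 0.17; edgeR adjusted p = 0.522), and DESeq2 gave an adjusted p of 0.847. A small insertion or deletion in exon 2 can leave the transcript in place, so this level does not check the genotype. TDRD3, the protein partner that TOP3B binds on chromatin and on mRNA, stood at 45.7 ± 15.9 CPM in WT and 38.3 ± 3.36 in KO (log2 fold change -0.26, SE 0.27; edgeR adjusted p = 0.715); without WT replicate 1 this log2 fold change was 0.15. FMR1, which encodes the RNA-binding protein FMRP of the same complex, stood at 70.3 ± 12.9 CPM in WT and fell to 35.3 ± 3.75 CPM in KO (log2 fold change -0.99, SE 0.25; DESeq2 adjusted p = 0.010). For FMR1 the edgeR adjusted p was 0.260 over all genes and 0.0244 adjusted over the list alone. The list of TOP3B partners and the FMRP family had 8 tested members with a median of -0.08 (camera adjusted p = 0.472). FMR1 was the 1 member past the threshold, by edgeR adjusted over the list alone and by DESeq2.

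NRIP1, a corepressor of nuclear receptors, was nearly lost from the KO clone. It fell from 196.7 ± 5.74 CPM in WT to 0.549 ± 0.137 CPM in KO (SD, n = 2 each), a difference of 342-fold (log2 fold change -8.42, SE 0.20; edgeR adjusted p = 0.00171; DESeq2 adjusted p = 1.14e-89). Its counts were 2606 and 2353 in the WT libraries and 5 and 11 in the KO libraries. It was the 1 gene of 12269 that edgeR called, with 0 higher and 1 lower in KO. With 1 KO library the same fold did not pass in edgeR (adjusted p = 0.156 without KO replicate 1 and 0.145 without KO replicate 2). At an unadjusted p under 0.05 edgeR gave 1372 genes, 610 higher and 762 lower, and limma-voom called 1 gene.

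DESeq2, an alternative fixed before the data were examined, called 187 of 12899 genes, with 65 higher and 122 lower in KO. Of these, 45 were at least 2-fold higher and 94 at least 2-fold lower. In 184 of the 187, which edgeR had also tested, the fold had the same direction in edgeR and the KO libraries lay on 1 side of both WT libraries. These genes were chosen on the same counts, so this direction and separation are no separate evidence for the calls. Across all tested genes such separation held for 47.0%, where chance gives 33.3%, with 2883 genes higher and 2878 lower in KO. The DESeq2 count was 85 without WT replicate 1, 721 without WT replicate 2, 75 without KO replicate 1 and 72 without KO replicate 2, and 54, 119, 43 and 42 of the 187 genes were still called. In simulated data 28.3% of genes that DESeq2 called were unchanged, against 14.7% for edgeR. These shares may not carry over, as edgeR called many more genes in the simulated data than here.

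**Figure D1:**
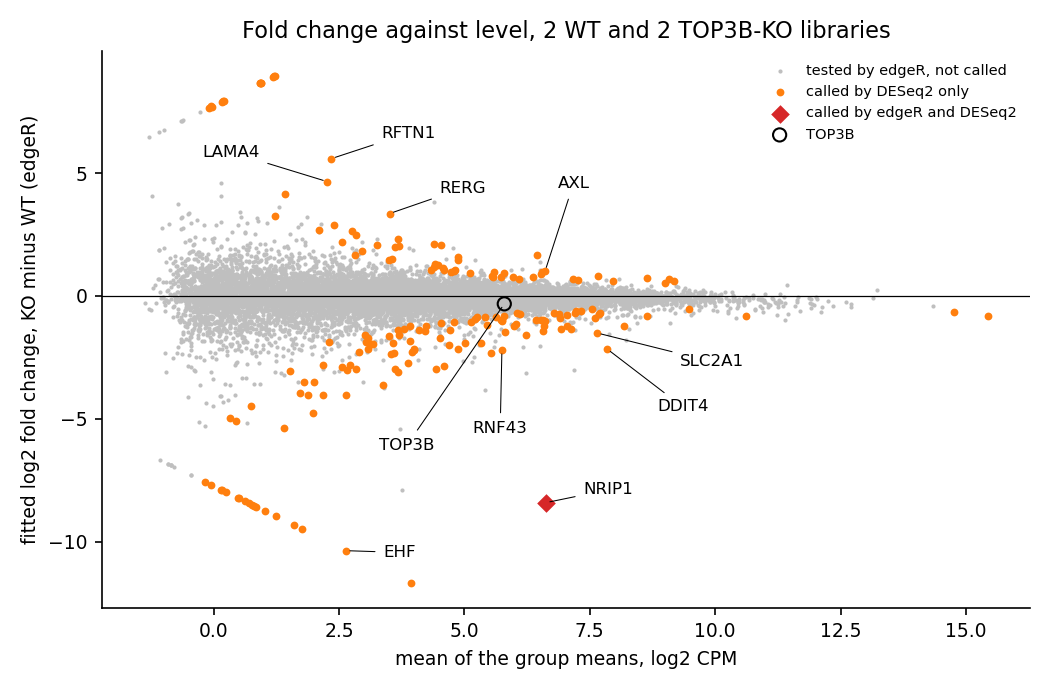
Each point is a gene tested by edgeR, with the mean of the WT and KO group means in log2 CPM on the horizontal axis and the fitted log2 fold change (KO minus WT) on the vertical axis. NRIP1 lies at -8.42 and is called by both tools, TOP3B lies at -0.32 among genes that were not called, and lines of points far from 0 are genes with no counts in 1 group, whose fitted fold depends on the prior count.

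The genes with the largest rise among the DESeq2 calls, chosen by the rule for named genes in a step added after the data were seen, were mostly expressed at low levels in WT cells. RFTN1, a lipid raft protein, went from 0.197 ± 0.0476 to 9.99 ± 1.84 CPM (log2 fold change 5.66, SE 0.85; DESeq2 adjusted p = 2.77e-08). LAMA4, a laminin chain of basement membranes, went from 0.364 ± 0.296 to 9.25 ± 2.61 CPM (4.69, SE 0.80; DESeq2 adjusted p = 2.86e-06). RERG, a small GTPase of the RAS family, rose from 2.02 ± 0.0814 to 20.7 ± 0.0654 CPM (3.36, SE 0.41; DESeq2 adjusted p = 5.85e-13). The others were TARID, a long antisense RNA, the nucleoside transporter SLC29A1, the DNA-binding proteins ARID3B and ZNF658, the membrane protein TMEM109, the chaperone partner DNAJC14 and the mismatch repair protein MSH6. Their log2 fold changes ran from 4.21 for TARID to 2.21 for MSH6, with DESeq2 adjusted p between 0.000224 (DNAJC14) and 0.0153 (ARID3B). The edgeR adjusted p of these 10 genes lay between 0.0729 (RERG) and 0.260 (ARID3B and SLC29A1).

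Several of the genes with the largest fall were not detected in KO. EHF, an ETS transcription factor of epithelial cells, had 12.4 ± 4.07 CPM in WT and 0 counts in KO, at least 116-fold lower (DESeq2 adjusted p = 1.76e-07). CPEB1, which controls cytoplasmic polyadenylation of mRNA, had 6.80 ± 0.461 CPM in WT and 0 counts in KO, at least 63.7-fold lower (DESeq2 adjusted p = 1.18e-05). CA9, a carbonic anhydrase induced by low oxygen, had 6.09 ± 1.31 CPM in WT and 0 counts in KO, at least 57.0-fold lower (DESeq2 adjusted p = 2.84e-05). BLOC1S5-TXNDC5 was at least 286-fold lower (DESeq2 adjusted p = 4.99e-10), but it is a readthrough gene that shares its sequence with its neighbours, so its estimate is uncertain. GMDS, an enzyme of GDP-fucose synthesis, had a log2 fold change of -4.77 (SE 0.95; DESeq2 adjusted p = 0.000213). The endosomal GTPase RAB15 (-5.43, SE 1.28; DESeq2 adjusted p = 0.00368), the transcriptional repressor ZBTB18 (-4.12, SE 1.1; DESeq2 adjusted p = 0.0178), the membrane protein ITM2B (-4.12, SE 1.19; DESeq2 adjusted p = 0.0391) and VPS33A, which acts in vesicle fusion (-4.06, SE 0.83; DESeq2 adjusted p = 0.000312), also fell. The WT libraries differed in these last genes, with 19.1 and 4.34 CPM for VPS33A and 12.6 and 4.67 CPM for ZBTB18. The edgeR adjusted p of the genes named here lay between 0.170 (EHF and CPEB1) and 0.388 (ITM2B).

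Genes of the hypoxia response and glycolysis were lower in the KO clone as a group. Of 32 tested members, 29 had a log2 fold change below 0, and in 24 both KO libraries lay below both WT libraries, against 2 the other way. The median was -0.61 (camera adjusted p = 1.17e-07; adjusted p = 0.621 with an estimated correlation). The glucose transporter SLC2A1 fell from 295.7 ± 75.3 to 103.9 ± 8.40 CPM (log2 fold change -1.50, SE 0.23; DESeq2 adjusted p = 5.87e-08). NDRG1, a growth regulator induced by hypoxia, fell from 47.8 ± 18.6 to 10.7 ± 0.122 CPM (-2.16, SE 0.36; DESeq2 adjusted p = 1.26e-06), and the histone demethylase KDM3A from 185.6 ± 12.3 to 79.3 ± 18.9 CPM (-1.22, SE 0.23; DESeq2 adjusted p = 4.82e-05). With CA9 these were the 4 members of smallest p. Over all genes edgeR called 0 members, with 12 at an unadjusted p under 0.05, and DESeq2 6 lower; adjusted over the list alone edgeR called 6 lower and DESeq2 10 lower. Placing CA9 at its bound could not move the median of -0.61, since that bound also lies below the median.

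**Figure D2:**
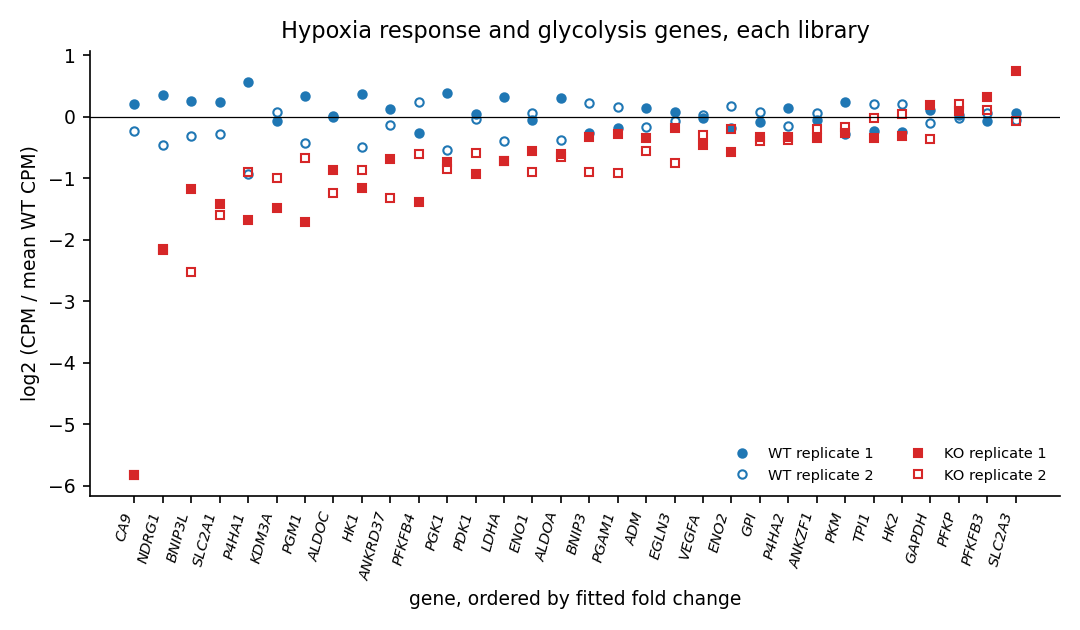
Log2 of CPM over the mean WT CPM is shown in each of the 4 libraries for the 32 hypoxia response and glycolysis genes, ordered by fitted fold change (blue circles, WT; red squares, KO; filled, replicate 1; open, replicate 2). In 24 genes both KO points lie below both WT points, and CA9, with 0 counts in KO, is drawn at its bound of 57.0-fold.

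Epithelial genes were also lower. Of 30 tested members, 23 had a log2 fold change below 0, and in 19 both KO libraries lay below both WT libraries, against 3 above. The median was -0.33 (camera adjusted p = 0.00110; adjusted p = 0.621 with an estimated correlation). Beside EHF, the related factor ELF3 fell from 122.2 ± 9.11 to 62.7 ± 7.04 CPM (log2 fold change -0.96, SE 0.20; DESeq2 adjusted p = 0.000390), and the keratin KRT19 from 1994 ± 353 to 1145 ± 86.5 CPM (-0.80, SE 0.19; DESeq2 adjusted p = 0.00290). CLDN4, a tight-junction protein, had a log2 fold change of -0.87 (SE 0.27; DESeq2 adjusted p = 0.0716). Adjusted over the list alone edgeR called 4 members lower, and DESeq2 called 6 lower and 1 higher; over all genes edgeR called 0, with 15 at an unadjusted p under 0.05, and DESeq2 3 lower. Placing EHF at its bound could not move the median of -0.33, since that bound also lies below the median.

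Genes of cholesterol synthesis had a median of -0.30 (camera adjusted p = 0.00986; adjusted p = 0.621 with an estimated correlation). Of 23 tested members, 20 had a log2 fold change below 0, and 12 had both KO libraries below both WT libraries, with 0 above. FDFT1, the squalene synthase, fell from 113.3 ± 27.2 to 57.9 ± 14.1 CPM (log2 fold change -0.97, SE 0.28; DESeq2 adjusted p = 0.0391). For INSIG1, IDI1 and NSDHL the log2 fold changes were -0.80, -0.54 and -0.38, with DESeq2 adjusted p of 0.223, 0.715 and 0.693. By edgeR 0 members passed, over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05, and by DESeq2 1 member did in both. Unlike the lists above, this one did not pass camera without WT replicate 1 (median -0.26, adjusted p = 0.0603) or without KO replicate 1 (median -0.21, adjusted p = 0.0679). Of the 27 lists tested, these 3 passed camera with the preset correlation and 0 passed with an estimated one or with fry. With these last 2 tests, 2 and 5 lists had an unadjusted p under 0.05. The estimated correlations of the hypoxia, epithelial and cholesterol lists were 0.014, -0.011 and -0.016, close to or below the preset 0.01. Their unadjusted camera p still rose from 4.33e-09, 8.14e-05 and 0.0011 to 0.0303, 0.0465 and 0.069. The size of the correlation therefore does not account for the difference. With an estimated correlation camera takes its degrees of freedom from the 4 libraries, so small p are hard to reach. Failing that test does not show that correlated genes made the shifts. Fry's mixed test, for change in either direction, passed 15.

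Single targets of signalling pathways passed by DESeq2 or by edgeR adjusted over the list alone, while edgeR called 0 of them over all genes. As lists, WNT targets, YAP/TAZ targets and stress response genes did not pass camera on log2 CPM. They passed on the DESeq2 statistic with the preset correlation (camera adjusted p = 0.00771, 0.0183 and 0.0390). With an estimated correlation on log2 CPM the camera adjusted p were 0.697, 0.697 and 0.758. The stress response list passed on the DESeq2 statistic with a median log2 fold change of -0.00074, so that pass does not show a shift of most members. RNF43, a feedback inhibitor of WNT signalling, fell from 88.3 ± 4.96 to 19.3 ± 1.92 CPM (log2 fold change -2.19, SE 0.22; DESeq2 adjusted p = 2.26e-19; edgeR adjusted p = 0.0729 over all genes and 0.000413 adjusted over the list alone). With EPHB2 (-0.79; edgeR adjusted p = 0.0448, adjusted over the list alone; DESeq2 adjusted p = 0.0676) it made up the 2 WNT target genes that passed in either tool adjusted over the list alone, and DESeq2 called 1 over all genes; AXIN2 had -0.97 (DESeq2 adjusted p = 0.290). The WNT list had 16 tested members with a median of -0.22 (camera adjusted p = 0.140), and 13 lay below 0; without WT replicate 1 the median was 0.06. DDIT4, an inhibitor of mTORC1 induced by stress, fell from 375 ± 19.3 to 84.1 ± 7.54 CPM (-2.15, SE 0.17; DESeq2 adjusted p = 4.60e-34; edgeR adjusted p = 0.000314, adjusted over the list alone). It was the 1 stress response gene of 23 called by edgeR adjusted over the list alone, where DESeq2 called 2, and by DESeq2 over all genes (list median -0.01, camera adjusted p = 0.617). AXL, a receptor tyrosine kinase, rose from 65.0 ± 3.92 to 129.9 ± 15.7 CPM (1.00, SE 0.20; DESeq2 adjusted p = 0.000151), and the angiomotin family member AMOTL2 from 119.4 ± 1.88 to 188.8 ± 21.2 CPM (0.66, SE 0.18; DESeq2 adjusted p = 0.0179). AXL, AMOTL2, F3 and CRIM1 were among 5 YAP/TAZ target genes called higher by edgeR adjusted over the list alone; DESeq2 called 2 over all genes and 5 adjusted over the list alone, and the list of 16 had a median of 0.20 (camera adjusted p = 0.116). Without WT replicate 1 the YAP/TAZ list passed, with a median of 0.32 (camera adjusted p = 0.0338), while the median was 0.11 without WT replicate 2 (0.578) and 0.11 without KO replicate 2 (0.477). Among immediate early genes KLF4 fell (-1.06, SE 0.24; DESeq2 adjusted p = 0.00153) and NR4A1 rose (1.18, SE 0.32; DESeq2 adjusted p = 0.0210), and they were the members called by either tool adjusted over the list alone. This list of 9 had a median of 0.14 (camera adjusted p = 0.339).

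**Figure D3:**
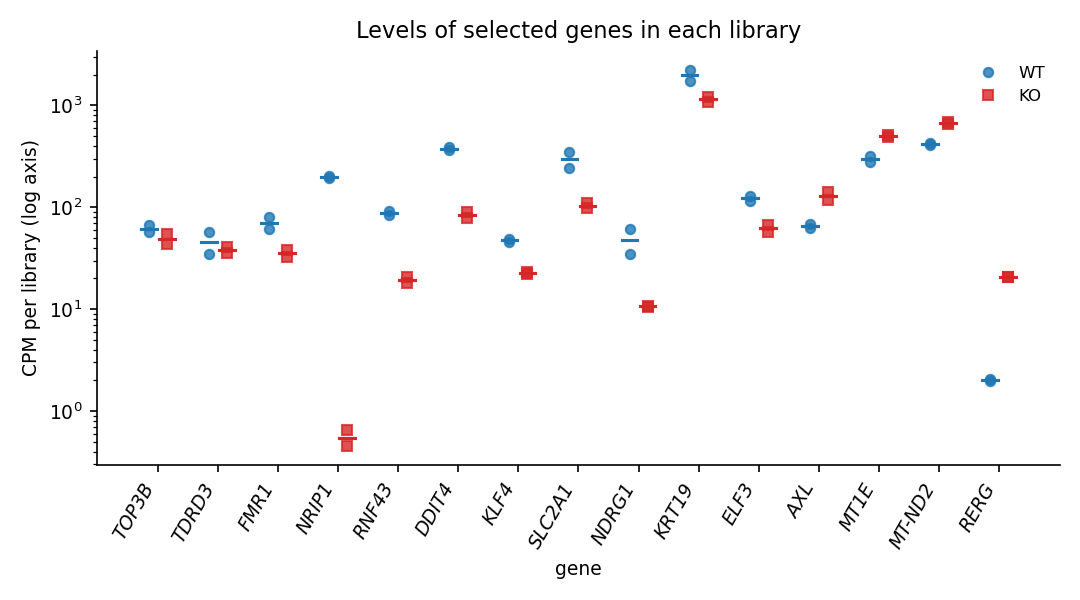
CPM of 15 genes in each library on a log axis, with 2 WT libraries (blue circles) and 2 KO libraries (red squares) per gene and a line at each group mean. NRIP1 lies at 0.452 and 0.646 CPM in KO against 200.8 and 192.7 in WT, while TOP3B lies at 43.9 to 66.5 CPM in all 4 libraries.

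Mesenchymal genes moved both ways. AXL is also in this list, S100A4 fell from 48.8 ± 2.21 to 27.1 ± 0.744 CPM (log2 fold change -0.84, SE 0.23; DESeq2 adjusted p = 0.0210), and ZEB1, a repressor of epithelial genes, had 15.7 ± 2.30 and 25.7 ± 0.971 CPM (0.72, SE 0.30; DESeq2 adjusted p = 0.319). The 9 tested members had a median of 0.33 (camera adjusted p = 0.233), with 2 higher and 1 lower by either tool adjusted over the list alone, and 1 each way by DESeq2 over all genes. The metallothionein MT1E rose from 298.5 ± 28.6 to 497.6 ± 14.1 CPM (0.74, SE 0.16; DESeq2 adjusted p = 0.000734). All 4 tested metallothioneins had a fold above 0, too few for a test of the list. With no filter on low counts 5 were tested and passed, with a median of 0.82 (camera adjusted p = 0.0237, preset correlation only). MT1E was the 1 called by either tool adjusted over the list alone. MT-ND2, a subunit of respiratory complex I, rose from 416.6 ± 18.1 to 668.8 ± 25.8 CPM (0.69, SE 0.14; DESeq2 adjusted p = 0.000512), while the 13 mitochondrially encoded mRNAs had a median of -0.03 (camera adjusted p = 0.710). Adjusted over the list alone edgeR called 1 of them and DESeq2 2, all higher. TNFAIP3, an inhibitor of NF-kappaB signalling, had 0 counts in WT and 4.54 ± 1.76 CPM in KO (DESeq2 adjusted p = 0.000331), and was the 1 call of either tool adjusted over the list alone. The 9 NF-kappaB target genes had a median of -0.25 with a mean of 0.69 (camera adjusted p = 0.403). The p53 target CD82 fell (-2.78, SE 0.78; DESeq2 adjusted p = 0.0315), with 0 calls by edgeR and 1 by DESeq2 adjusted over the list alone, and the 27 p53 target genes had a median of 0.10 with a mean of -0.10 (camera adjusted p = 0.710).

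Genes for translation were measured beside a share of ribosomal protein counts that was 8.18% and 6.61% in the WT libraries and 6.51% and 6.17% in the KO libraries, the highest in WT replicate 1. The 78 cytosolic ribosomal protein genes had a median of -0.20 (camera adjusted p = 0.140). The list passed on the DESeq2 statistic (camera adjusted p = 0.00214) and without WT replicate 2 (median -0.32, camera adjusted p = 0.00114), against -0.04 without WT replicate 1 and adjusted p = 0.758 with an estimated correlation. DESeq2 called 1 of these genes, RPL36A, lower (log2 fold change -0.54, SE 0.16; DESeq2 adjusted p = 0.0398). Among 16 translation factor and TOP mRNA genes (median -0.14, camera adjusted p = 0.373), EEF2, the elongation factor of translocation, fell (-1.21, SE 0.32, DESeq2 adjusted p = 0.0178). In this list 12 members had a fold below 0 and 4 above. The counts of EEF1A1, also in the list, went up, from 540 and 947 in WT to 1440 and 1940 in KO. Where such genes share reads with copies, these estimates are uncertain. LYAR was the 1 call of DESeq2 (DESeq2 adjusted p = 0.0195) among 24 ribosome biogenesis and MYC target genes, which had a median of 0.10 with a mean of -0.04 (camera adjusted p = 0.391). For LYAR, EEF2 and RPL36A the edgeR adjusted p was 0.388, 0.337 and 0.326. Adjusted over the list alone edgeR called 0 genes in these lists, and DESeq2 called 1, 4 (1 higher) and 1, in the order of the lists above.

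Factors that process R-loops, the structures named in the study's aim, had 36 tested members with a median of 0.07 (camera adjusted p = 0.224). The median was 0.22 without WT replicate 1 (camera adjusted p = 0.0592), 0.14 without KO replicate 1 (0.147) and 0.04 without KO replicate 2 (0.478), and the list passed on unfiltered log2(RPKM + 1) (median 0.14, camera adjusted p = 0.0209; adjusted p = 0.697 with an estimated correlation on log2 CPM). BARD1, PIF1 and THOC1 had log2 fold changes of 0.89, 0.45 and 0.53, and 0 members passed by edgeR, over all genes or adjusted over the list alone (0.249 for each of these genes), or by DESeq2; 7 had an edgeR p under 0.05 unadjusted. The 7 topoisomerases and tyrosyl-DNA phosphodiesterases had a median of 0.26 (camera adjusted p = 0.478), with 0.27 for TOP3A and -0.40 for TOP2B, neither past the threshold. The 19 genes of the BTR dissolvasome and homologous recombination had a median of 0.15 (camera adjusted p = 0.585), with 1 higher by DESeq2 adjusted over the list alone, PALB2. The 23 genes of nuclear RNA surveillance and 3' end processing had a median of -0.04 (camera adjusted p = 0.972).

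The other lists did not pass camera on log2 CPM of the filtered genes either. Medians were -0.31 for 11 replication-dependent histone genes (camera adjusted p = 0.140), -0.32 for 15 neuronal and synaptic genes (0.140), -0.16 for 11 intestinal stem cell genes (0.201) and -0.17 for 20 interferon-stimulated genes (0.653). With no filter on low counts 24 neuronal genes passed, with a median of -0.55 (camera adjusted p = 0.0305; adjusted p = 0.697 with an estimated correlation on the filtered genes), and without KO replicate 2 the median was -0.54 (0.136). Among the neuronal genes NCAM1 and CNTNAP2 were called lower by edgeR adjusted over the list alone (both 0.0472), and by neither tool over all genes. Adjusted over the list alone DESeq2 called 2 neuronal genes lower, EPHB2 lower among intestinal stem cell genes and CENPF higher among proliferation genes. Proliferation genes, 43 in number, had a median of -0.02 with a mean of 0.03 (camera adjusted p = 0.403), 17 genes of MAPK pathway output had 0.04 (0.751), 5 cancer-testis genes had -0.19 (0.559) and 10 neighbours of TOP3B on chromosome 22 had 0.01 (0.710). Markers of other cell types were scarce, with tested members numbering 1 for endothelial, 0 for erythroid, 1 for fibroblast, 3 for hepatocyte and kidney and 2 for leukocyte genes; none of their members exceeded a mean of 9.36 CPM over the 4 libraries. Genes of intestinal differentiation had 3 tested members, of which 0 were called by edgeR or DESeq2 and 1 had an edgeR p under 0.05 unadjusted.

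Long genes were examined because topoisomerases relieve the torsion that transcription of long templates builds up. The 2292 genes spanning over 100 kb in GRCh38 had a median log2 fold change of -0.03, and camera gave p = 0.628 for them (0.696 with an estimated correlation). Medians by span were 0.02 for 2530 genes under 10 kb, -0.00 for 3361 genes up to 30 kb, -0.04 for 4047 genes up to 100 kb, -0.03 for 1888 genes up to 300 kb and 0.00 for 404 longer genes. Spearman's rho of span and fold change across genes, which are not independent replicates, was -0.0379, and it ran from -0.0749 to 0.0150 over the 4 pairs of a KO and a WT library. The sign and size of rho depended on processing. It was 0.0599 with no filter on low counts, and more negative than reported on filtered log2(RPKM + 1) and log2(RPKM + 0.1). The median of the long genes was positive only where that of all genes was higher still, such as 0.13 beside 0.14 with total counts as the only scaling.

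No chromosome passed the test for a shift as a whole. Of 24 tested with camera, counting the mitochondrial one, 0 passed after adjustment and 1 had an unadjusted p under 0.05. This was chromosome 22, which carries TOP3B, with a median of 0.08 over 323 genes (camera adjusted p = 0.702). NRIP1 lies on chromosome 21, whose 117 genes had a median of 0.03 (camera adjusted p = 0.995).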

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

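Robust dispersions, the GC correction, the restriction to genes with no 0 and the refits of DESeq2 were chosen only after the data were seen. Each value was set against each alternative. For the 48 values of single genes, directions and lists, 628 such comparisons kept direction and side of the threshold. Of the others, 109 passed it only in the alternative, 12 no longer did, 20 moved and 8 reversed. Most of the single genes were chosen as DESeq2 calls that edgeR did not call. For them the same side meant staying uncalled, and passing with DESeq2 was fixed by that choice. Only NRIP1 and the 3 lists passed as reported, so only they could stop passing. These counts are therefore no measure of how stable the results are. For the 6 values that answer a comparison, 70 stayed and 26 moved. The edgeR count of 1 gene was the same with RLE factors, the stricter filter, the replicate block, limma-voom, robust dispersions, glmTreat, the other thresholds and a GC correction. It was 187 with DESeq2, 5 with upper-quartile factors, 42 with total counts only, 34 with no filter on low counts, 7 for genes with no 0, 6 on log2(RPKM + 0.1), 0 on log2(RPKM + 1) and 0 there with no filter. Leaving out single libraries gave 0 to 575; the group with 1 library was then assumed to vary like the other. The DESeq2 count of 187 was 72 to 721 without single libraries and 105 with the replicate block, 84 of them among the 187. NRIP1 kept its direction in every fit and missed the threshold without either KO library and on log2(RPKM + 1) (adjusted p = 0.121, and 0.400 with no filter), and its adjusted p ran from 1.14e-89 to 0.400. The TOP3B log2 fold change ran from -0.49 to -0.14 and did not pass in any fit. TDRD3 ran from -0.56 to 0.15 without single libraries. Of 3 lists passing, 7 passed with DESeq2 values (also ribosomal protein, WNT, YAP/TAZ and stress response genes), 5 with no filter (also neuronal genes and metallothioneins), 6 on unfiltered log2(RPKM + 1) (also R-loop factors, metallothioneins and ribosome biogenesis genes), 0 with an estimated correlation and 0 with fry; outside those last 2 tests the hypoxia and epithelial lists passed in every fit, and the cholesterol list failed without WT replicate 1 or KO replicate 1. The rho of gene length was 0.0599 with no filter, -0.15 on log2(RPKM + 1), -0.105 on log2(RPKM + 0.1) and 0.0273 on unfiltered log2(RPKM + 1). The median of genes over 100 kb turned positive with that of all genes and stayed below it each time: it was 0.016 with upper-quartile factors, 0.13 with total counts only, 0.0126 on log2(RPKM + 1), 0.0635 on log2(RPKM + 0.1), 0.00193 on unfiltered log2(RPKM + 1) and 0.0306 with a GC correction, and ran from -0.0663 to 0.00305 without single libraries. Beside these the median of all genes, -0.01 as reported, was 0.03 with upper-quartile factors, 0.14 with total counts only, 0.04 on log2(RPKM + 1), 0.11 on log2(RPKM + 0.1), 0.03 with a GC correction and 0.02 without WT replicate 2. For the changes in counts of genes and lists, in TDRD3 and in rho the cause was not tested. With total counts only, 15 genes were higher and 27 lower. Chromosomes passing stayed at 0 in every fit run. A count of 0 allows up to 0.271 CPM in the library with the fewest counts. In simulated data edgeR recovered 19.6% of 2-fold changes, which may not carry over to these libraries.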

Other observations

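The tests of the gene beside NRIP1, of genes whose place is unknown, of the clone, of culture conditions and on runs of adjacent genes were chosen only after the result was seen, as were the genes named in the next paragraph.

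Other DESeq2 calls fell outside the rule for named genes. SEMA3A, a secreted guidance cue for axons and vessels, rose from 8.85 ± 0.0121 CPM in WT to 37.4 ± 1.76 in KO (SD, n = 2 each; log2 fold change 2.08, SE 0.28; DESeq2 adjusted p = 1.78e-10), and DPYSL3, which acts in the signalling of such cues, from 3.64 ± 0.517 to 15.6 ± 1.65 CPM (2.10, SE 0.42; DESeq2 adjusted p = 0.000220). The matrix genes VCAN (0.89, SE 0.18; DESeq2 adjusted p = 0.000426) and COL12A1 (0.62, SE 0.18; DESeq2 adjusted p = 0.0398) rose too. The serotonin receptor HTR7 fell from 175.1 ± 10.4 to 68.1 ± 1.61 CPM (-1.36, SE 0.17; DESeq2 adjusted p = 5.48e-12), the 14-3-3 protein YWHAQ from 42.7 ± 6.13 to 5.85 ± 0.80 CPM (-2.87, SE 0.31; DESeq2 adjusted p = 8.34e-17), the scaffold MAPK8IP1 from 23.0 ± 0.767 to 2.69 ± 0.0984 CPM (-3.09, SE 0.38; DESeq2 adjusted p = 5.85e-13) and S100A14 from 38.5 ± 9.40 to 4.81 ± 1.17 CPM (-2.98, SE 0.37; DESeq2 adjusted p = 7.45e-13). Their edgeR adjusted p lay between 0.0729 (MAPK8IP1) and 0.304 (COL12A1).

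28 genes had 0 counts in both libraries of 1 group and at least 20 in each library of the other, 17 of them at 0 in KO and 11 at 0 in WT; pairing the libraries across groups gave 7 and 8 such genes. Those at 0 in KO included MIR210HG, the host of a microRNA induced by hypoxia (41 and 61 counts in WT), the neuronal kinesin KIF5A and the phosphodiesterase PDE4D. Those at 0 in WT included the collagen receptor DDR2, the transcription factor IKZF3 and the phosphatase PTP4A3.

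NRIP1 fell 342-fold in the KO clone. A deletion reaching its nearest expressed neighbour, USP25, is argued against, since USP25 kept a KO to WT ratio of 0.824. USP25 lies after NRIP1 in gene order, and no gene of at least 5 CPM was found before it. A deletion reaching away from USP25 was therefore not tested. Reads assigned to genes that overlap it are argued against too: 0 genes placed by GENCODE 29 overlap NRIP1, and with the rise of any 1 of the 273 genes of unknown place its summed level in KO would reach at most 0.104 of WT. A lesion that spares USP25, or silencing at NRIP1, that arose in the clone may account for the loss. With 1 KO clone this cannot be told apart from an effect of TOP3B.

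Hypoxia response and glycolysis genes were lower in KO, with a median of -0.61. WT replicate 1 alone is argued against, as the median was -0.43 without it (camera adjusted p = 2.89e-06), and so is a GC trend, as the median was -0.60 with a GC correction (camera adjusted p = 3.89e-09). These are calls with the preset correlation, and with all libraries the list had adjusted p = 0.621 with an estimated correlation and 0.0563 with fry. A difference in density, medium or oxygen when RNA was taken may also lower these genes, and with 1 KO clone and no record of the cultures it cannot be told apart from genotype.

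Of 2 runs of adjacent genes lower in KO, the strongest windows of 40 genes were TMEM170A to MTHFSD on chromosome 16, with a median of -0.49 or 71.1% of WT (31 genes below 0, 25 with both KO libraries below both WT libraries, permutation p = 6e-05), and TAF7L to PLS3 on chromosome X, with -0.41 or 75.3% of WT (31 and 26 genes, permutation p = 0.00158). Chance order is argued against by the larger p of 0.00158 over 100000 random gene orders. That p covers the windows of 40 genes only, tried after blocks of 20 genes in which no block on chromosome X passed. A single library is argued against for chromosome X. The highest median over its KO and WT pairs was -0.25 in the joined run of 90 genes and -0.38 in its strongest window. For chromosome 16 a single library stays open. In the joined run of 50 genes the highest pair median was -0.0957, past the line set for that cause. In the window it was -0.40 and not past that line, and the cause required both. The window was chosen as the strongest after the joined runs were seen. A GC trend stays open for both. A GC correction moved the medians of the joined runs of chromosomes 16 and X from -0.35 and -0.36 to -0.27 and -0.21. Those of the windows moved to -0.42 and -0.32. For windows of 40 genes 95% of random orders stay within 0.330, and that bound was also used for the longer joined runs. The window on chromosome 16 stayed past it. The correction also moved the median log2 fold change of all genes, from -0.01 to 0.03. Fewer copies of these 2 segments in the clone may also account for them. Losing the only copy of a segment in every cell would remove its transcripts, unlike the 71.1% and 75.3% of WT seen here. With no DNA measured, the copies in WT and KO cells are not known, and a partial loss cannot be told apart from regulation.

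Windows past the bound numbered 8 of 1006 for KO against WT and 0 for either other split of the 4 libraries. The 8 windows lie in the 2 runs above. The largest medians of the other splits were 0.168 and 0.225 in size. The bound came from random orders of KO against WT, so the other splits were not judged against their own random orders. In the blocks of 20 genes tried before, 1 of 530 passed its bound, with a median of -0.50 (permutation p = 0.031). This was OSGIN1 to MTHFSD in the run of chromosome 16, and no block on chromosome X passed. Genes of these runs called lower by DESeq2 included MPHOSPH6 (-2.29, DESeq2 adjusted p = 0.000970), GCSH (-0.88, DESeq2 adjusted p = 0.0126) and COX4I1 (-1.33, DESeq2 adjusted p = 0.0152) on chromosome 16 and TMEM164 (-1.11, DESeq2 adjusted p = 0.0115) on chromosome X.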
